A study of Mus musculus with 18 samples.

How the data were processed

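RNA of P14 testis, P18 testis and spermatocytes isolated at P18 from Zfp541 Het and KO mice (C57BL/6J) was measured in 18 libraries, 3 in each of 6 groups. Per the labels, total RNA was extracted with Trizol, poly(A) RNA was isolated with NEBNext reagents and libraries were made with a NEBNext Ultra II kit; no strand setting is given in the sources used here. The authors deposited RPKM (reads per kilobase of gene per 1e6 reads) for P14 testis and P18 spermatocytes and FPKM (fragments in place of reads) for P18 testis. Each library had 1 table with a gene symbol and a value. Gene lengths were not taken from these tables but from the merged exons of the GRCm38 annotation supplied. The labels name CASAVA 1.9, STAR 2.6.1a, featureCounts, edgeR 3.28.1 and GRCm38 without stating what each step did, and these runs were made by the authors and not repeated here.

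The deposited values hold no counts. In each library the low values multiplied by gene length fell on whole multiples of 1 step (91.53% to 98.89% of the low values, within the rounding of the values), and that step gave the total reads behind the library: 17.96 to 21.12 M (megareads) at P14, 12.81 to 16.95 M in P18 testis and 9.26 to 18.31 M in spermatocytes. Reads read back in this way were used for the scaling and for 1 alternative. Totals were the sums the authors divided by and not a count of raw reads. Intervals for counting error were not computed, since the spread between replicates was used throughout.

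Symbols shared by more than 1 gene (190 at P14, 217 at P18, at most 0.3% of the summed values) were left out, and 829 older symbols were renamed with the synonyms of the RefSeq annotation. Comparisons across ages used only genes whose values gave whole reads with the same annotated length in both sets. This left out genes whose model differed (42556 had 1 length in all 18 libraries). Comparisons between spermatocytes and testis at P18 were not limited in this way. No sample was left out, and the deposited table values were the only measurements used. No library was a copy of another by the read counts read back. Coordinates came from the GRCm38 annotation supplied, and the share of each gene's 50-mers found elsewhere among annotated genes was counted from its exons.

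Values were rescaled by trimmed means of M values (30% and 5% trims), coded from the published formula with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and R 4.3.3, and figures were drawn with matplotlib 3.10.9. Each of the 3 comparisons of KO with Het had its own fit of 6 libraries, and both interactions, P18 against P14 testis in Het and in KO, and spermatocytes against testis in Het had fits of 12 libraries, 8 comparisons in all. Genes with a value of at least 1 in at least 3 libraries were tested with limma 3.58.1 on log2 of the value plus 0.5, with an intensity trend and robust variance moderation, and two-sided p values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Because group means are given after rescaling, they differ slightly between fits. The plan fixed before the files were opened was a count model with size factors; it was replaced by limma on log values because the deposited unit was RPKM or FPKM and not counts.

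A set of 23 gene lists was fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes, except where an addition is named. The lists cover partner proteins, spermatogonia, meiotic entry, break formation, the chromosome axis, the pachytene programme, the G2 to metaphase I cell cycle, the piRNA pathway, round spermatids, axonemes, autosomal retrogenes, silenced sex chromosome genes, Sertoli, Leydig, myoid, macrophage, endothelial and erythroid markers, p53 targets, interferon-stimulated genes, immediate-early and heat-shock genes, and mitochondrial and ribosomal protein genes. Each list was tested with camera in limma with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals; counts were also adjusted over the list alone. Overlaps were tested with Fisher's exact test over genes tested in both comparisons.

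Named genes were Zfp541, the 6 partner genes, up to 2 risen and 2 fallen members of each list, and, in each KO comparison and interaction, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with at least 5 counts per 1e6 in the higher group and no overlap between the libraries of the groups (5 per direction for age and fraction). With 3 libraries against 3, chance gives no overlap for 10% of genes. Not every gene the rule takes is printed, and genes named outside it are said to be.

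The fit was tested on simulated data with the depths of these libraries. All genes of a comparison were given 1 spread, a dispersion of 0.005 at P14, 0.018 in P18 testis and 0.0555 in spermatocytes. The P14 value was the lowest allowed. Of genes changed by a factor of 1.5, 2 or 4, limma called 40.3%, 86.6% and 93.9% at P14, 7.46%, 44.8% and 89.4% in P18 testis and 1.49%, 11.9% and 86.4% in spermatocytes, with 11, 9 and 9 false calls, so at P18 simulated folds of 1.5 and 2 were mostly missed. Neither this limit nor the shares called at P14 carry over to the fits of the deposited values. There, most calls at P18 lay under a factor of 2, while the 2 higher and 30 lower calls at P14 were all of at least that factor.

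Alternatives were median-of-ratios size factors, no filter, a stricter filter of 1 count per 1e6, a minimum log2 change of 1, a block for replicate number, 1 fit over all 18 libraries, the estimated correlation, leaving out each library in turn, and, chosen after seeing the data, pseudocounts of 0.1 and 1, the values as deposited without rescaling, voom on the recovered reads, and the sets of genes that change with age without genes of at least 5% shared 50-mers. Replicate numbers do not pair the samples as far as the labels state, so no paired result is given in the results. Other splits of the libraries were counted for each comparison.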

Results

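Poly(A)-selected RNA of 18 mouse libraries (C57BL/6J) was sequenced from heterozygous (Het) and knockout (KO) animals for Zfp541, a zinc-finger protein gene with ELM2 and SANT domains that is expressed in male germ cells. The 6 groups were P14 testis, P18 testis and spermatocytes isolated at P18, each as Het and KO with 3 libraries. The labels call them 3 biological replicates and do not state further whether the replicates are separate animals. At P14 the most advanced germ cells of the mouse testis are early pachytene spermatocytes, and at P18 they are late pachytene to diplotene spermatocytes. The libraries held 17.96 to 21.12 M reads (megareads) at P14, 12.81 to 16.95 M in P18 testis and 9.26 to 18.31 M in spermatocytes, as read back from the step size of the deposited values. Between 14917 and 18584 genes reached a value of 1 per library. A single read on a gene of 1 kb gave a value of 0.0473 to 0.108, so levels below about this size were near the limit of detection. Levels are group means ± SD (n = 3 libraries) of RPKM or FPKM after rescaling, fold changes are log2 values ± SE, and coordinates are those of GRCm38.

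Zfp541 itself (ENSMUSG00000078796.4, chromosome 7, 16061814 to 16096334) was lower in the KO libraries of all 3 sets, and transcript remained in each. At P14 its level was 8.66 ± 0.983 in Het and 4.04 ± 0.954 in KO, a log2 difference of −1.03 ± 0.16 that did not pass the test (adjusted p = 0.0903), although no KO library reached the level of a Het library. In P18 testis it fell from 25.2 ± 4.52 to 10.3 ± 1.05 (−1.25 ± 0.14, adjusted p = 0.00492, n = 3 and 3). In P18 spermatocytes it fell from 43.6 ± 12.6 to 12.2 ± 1.01 (−1.75 ± 0.20, adjusted p = 0.000795, n = 3 and 3). The P14 difference passed under a stricter filter (adjusted p = 0.0205), on recovered reads with voom (adjusted p = 0.009) and without KO replicate 3 (adjusted p = 0.0328).

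Of 6 genes for proteins reported in complexes with ZFP541, Kctd19 moved most. Kctd19 (chromosome 8, 105382807 to 105413502), a BTB-domain protein gene of spermatocytes, stood at 15.8 ± 2.18 in Het and 8.29 ± 2.64 in KO at P14 (−0.92 ± 0.22, adjusted p = 0.253). It fell from 69.4 ± 14.9 to 23.1 ± 0.776 in P18 testis (−1.55 ± 0.15, adjusted p = 0.0042) and from 110 ± 41.2 to 29.1 ± 2.43 in spermatocytes (−1.85 ± 0.24, adjusted p = 0.00133). Trerf1, an ELM2-SANT protein gene, rose in P18 testis (0.41 ± 0.09, adjusted p = 0.0215) and in spermatocytes (0.75 ± 0.12, adjusted p = 0.00282). Of the histone deacetylase genes, Hdac1 fell in P18 testis by 0.30 ± 0.07 on the log2 scale (adjusted p = 0.0312) and Hdac2 rose in spermatocytes from 32.5 to 44.6 (0.45 ± 0.09, adjusted p = 0.00663). Dnttip1 and Elmsan1 passed in no KO comparison, with differences of 0.06 and 0.03 at P14, −0.14 and 0.40 in P18 testis and −0.10 and 0.18 in spermatocytes. Elmsan1 passed in P18 testis only with voom (adjusted p = 0.0484). At P14 none of the 6 passed (Hdac1 −0.01, Hdac2 −0.07, Trerf1 0.15) and 1 fell when adjusted over the list alone. The list did not pass as a set at P14 (median 0.01, adjusted p = 0.817). In P18 testis it had 1 higher and 2 lower members, the same counts adjusted over the list alone (median −0.01, adjusted p = 0.732). In spermatocytes it had 2 higher and 1 lower, again the same adjusted over the list alone, with a median of 0.07 and a mean of −0.10 (adjusted p = 0.382). In P18 testis the calls of Hdac1 and Trerf1 ended without Het replicate 2, KO replicate 2 or KO replicate 3 (adjusted p = 0.0534 to 0.109 over all fits without 1 library that ended either call). That of Hdac1 also ended without KO replicate 1, as deposited and without a filter, and that of Trerf1 without Het replicate 3. The Hdac1 difference in spermatocytes (−0.04, adjusted p = 0.824) turned positive under 4 alternatives, up to 0.2 as deposited. That of Dnttip1 there turned positive in 1 fit over all 18 libraries (0.032) and as deposited (0.141). At P14 the differences of Elmsan1 (−0.044 to 0.082) and Hdac1 (−0.053 to 0.027) took both signs without single libraries.

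**Figure D1:**
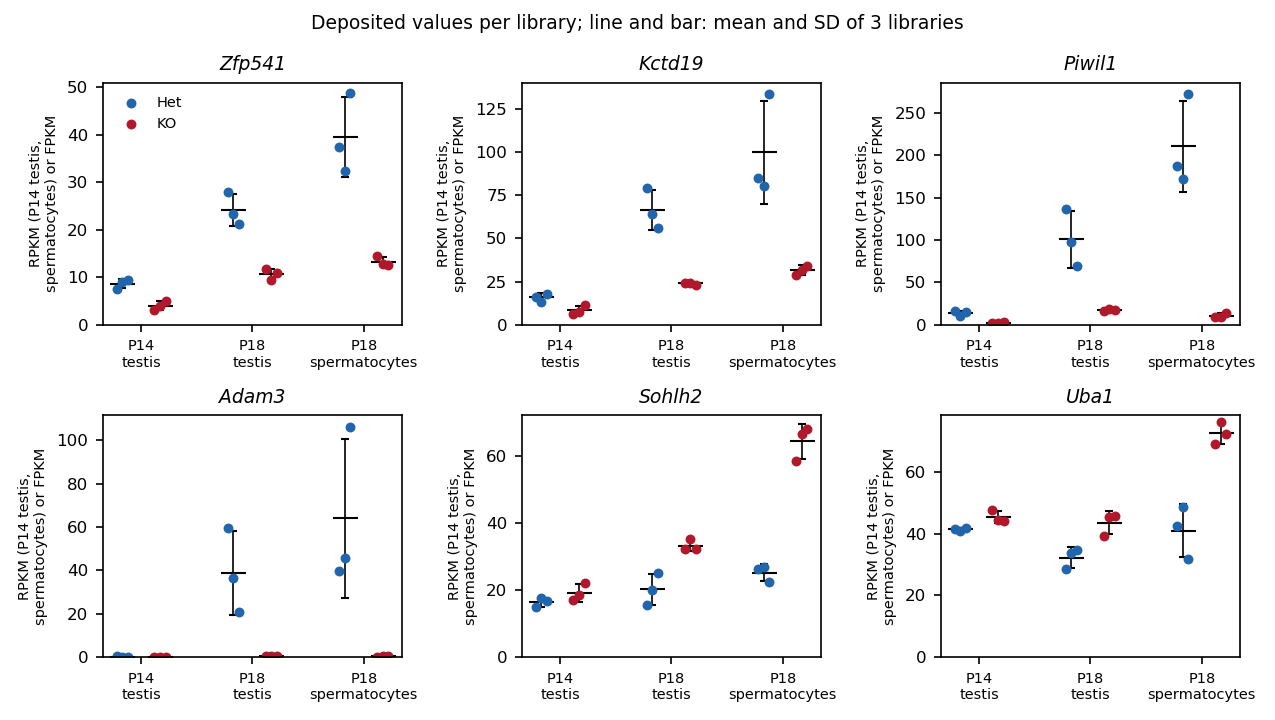
Deposited RPKM (P14 testis, P18 spermatocytes) or FPKM (P18 testis) of 6 genes on linear axes; each point is 1 library, blue Het and red KO, and the line and bar are the mean and SD of 3 libraries. Zfp541, Kctd19, Piwil1 and Adam3 lay lower in every KO library than in any Het library of the same set. Uba1 lay higher without overlap in all 3 sets and Sohlh2 in both P18 sets.

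In P14 testis few transcripts differed between KO and Het, and nearly all of them were lower in KO. The comparison asked which genes were differentially expressed between the genotypes at that age. Crisp2 (chromosome 17, 40764020 to 40807003), a cysteine-rich secretory protein gene of sperm, fell from 4.41 ± 1.03 to 0.319 ± 0.115 (−2.57 ± 0.19, adjusted p = 0.0206). Piwil1 (chromosome 5, 128702524 to 128755474), which encodes the piRNA-binding protein MIWI, fell from 13.5 ± 2.89 to 2.32 ± 0.778 (−2.33 ± 0.23, adjusted p = 0.036). Zmynd10 (chromosome 9, 107547298 to 107551319), needed to assemble dynein arms, fell from 5.26 ± 1.49 to 0.618 ± 0.16 (−2.34 ± 0.21, adjusted p = 0.0206). Spata4 (chromosome 8, 54600781 to 54610098) fell from 7.30 ± 1.82 to 0.910 ± 0.372 (−2.48 ± 0.26, adjusted p = 0.0362). Dkkl1, an acrosomal protein gene (chromosome 7, 45207519 to 45212147), fell by 2.10 ± 0.18 (adjusted p = 0.0206). Cetn1, a centrin retrogene (chromosome 18, 9615524 to 9619478), fell by 1.98 ± 0.17 and Tekt1, a ciliary tektin, fell by 1.82 ± 0.16, both with an adjusted p of 0.0206. Clec2m (−1.91 ± 0.21, adjusted p = 0.0362) and Cfap65 (−1.87 ± 0.23, adjusted p = 0.048) fell as well. Without a filter all of these calls but that of Crisp2 ended. With a pseudocount of 0.1 those of Piwil1, Spata4, Clec2m and Cfap65 ended. That of Cfap65 also ended with median-of-ratios scaling, as deposited, with a pseudocount of 1 and with voom, where its difference was larger (−2.87).

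Of 17688 genes tested at P14, 2 rose and 30 fell, all by at least 1 on the log2 scale; at an unadjusted p under 0.05 the counts were 482 and 1048. The 2 that rose, Gm37338 and Gm23017, stand outside the rule for named genes and were chosen after their values were seen; Gm37338 was listed at 0 in all 3 Het libraries. Lists of spermatocyte and sperm genes were lower in KO as sets. In the pachytene transcription programme 4 of 27 members fell (17 adjusted over the list alone), with a median of −0.41 (adjusted p = 3.8e-21, and adjusted p = 0.338 with an estimated correlation). In the axoneme and cilium list 3 of 21 fell (16 adjusted over the list alone, median −0.60, adjusted p = 2.12e-18, and adjusted p = 0.338 with an estimated correlation). Of the piRNA pathway 1 of 23 fell (12 adjusted over the list alone, median −0.27, adjusted p = 3.24e-11, and adjusted p = 0.469 with an estimated correlation). In the round spermatid and acrosome list 1 of 9 fell (6 adjusted over the list alone, median −0.48, adjusted p = 3.3e-07, and adjusted p = 0.356 with an estimated correlation). Of the autosomal retrogenes of X-linked genes 1 of 10 fell (7 adjusted over the list alone, median −0.34, adjusted p = 2.64e-10, and adjusted p = 0.338 with an estimated correlation).

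Lists of earlier germ-cell stages held no called member at P14. Spermatogonial genes lay slightly higher as a set (27 tested, 1 lower adjusted over the list alone, median 0.14, adjusted p = 4.14e-05, and adjusted p = 0.532 with an estimated correlation). The chromosome axis and synaptonemal complex list lay lower (20 tested, 1 lower adjusted over the list alone, median −0.18, adjusted p = 1.24e-05, and adjusted p = 0.542 with an estimated correlation). Break formation and strand exchange (34 tested, 1 lower adjusted over the list alone, median −0.06) also passed, with an adjusted p of 0.00721 and an adjusted p = 0.86 with an estimated correlation. So did the G2 to metaphase I cell cycle (35 tested, 2 lower adjusted over the list alone, median −0.06, adjusted p = 0.0143, and adjusted p = 0.818 with an estimated correlation). Meiotic entry (24 tested, median 0.04, adjusted p = 0.735) and the sex chromosome genes silenced in pachytene (41 tested, median 0.01, adjusted p = 0.282) did not. None of the somatic and general lists had a called member. Sertoli markers passed as a set (25 tested, median 0.08, adjusted p = 0.000398, and adjusted p = 0.537 with an estimated correlation). Cytoplasmic ribosomal proteins did too (50 tested, median 0.04, adjusted p = 0.00167, and adjusted p = 0.818 with an estimated correlation). Leydig (14 tested, median −0.22), peritubular myoid (10, −0.04), macrophage (16, −0.08), endothelial (8, 0.01) and erythroid markers (5, 0.17) did not pass. The p53 target (22, 0.05), interferon-stimulated (13, −0.01), immediate-early and heat-shock (21, 0.11, with 1 higher adjusted over the list alone) and mitochondrially encoded lists (13, −0.03) did not pass. The P14 counts rested on single libraries: without Het replicate 1, Het replicate 3, KO replicate 1 or KO replicate 2 the count was 0 in both directions. Without Het replicate 2 it was 3 higher and 12 lower, and without KO replicate 3 it was 4 higher and 124 lower. The set calls of break formation, the G2 to metaphase I list and ribosomal proteins ended without Het replicate 3 (adjusted p = 0.18 each) or KO replicate 1 (adjusted p = 0.577, 0.0767 and 0.141). That of the G2 to metaphase I list also ended without KO replicate 2 (adjusted p = 0.101). In 1 fit over all 18 libraries the set calls of break formation, G2 to metaphase I and Sertoli genes ended (adjusted p = 0.0638, 0.266 and 0.193).

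In P18 testis genes of late spermatocytes and of sperm structures were far lower in KO than in Het, and smaller rises were seen in genes of early germ cells, somatic cells and the X chromosome. The comparison asked the same question as at P14, at the later age. The deepest falls reached levels below 1 in KO. Hspb9 (chromosome 11, 100713850 to 100714575), a small heat-shock protein gene of testis, fell from 64.3 ± 32 to 0.990 ± 0.331 (−5.35 ± 0.36, adjusted p = 0.0042). Adam3 (chromosome 8, 24677225 to 24725852), a sperm surface protein gene needed for fertilisation, fell from 40.9 ± 21.9 to 0.569 ± 0.0997 (−5.14 ± 0.38, adjusted p = 0.0042). Qrich2 (chromosome 11, 116441325 to 116466241), a gene of the sperm flagellum, fell from 33.6 ± 17.6 to 0.237 ± 0.0206 (−5.40 ± 0.36, adjusted p = 0.0042). The uncharacterised gene 1700123L14Rik (chromosome 6, 96164497 to 96166243) fell from 49.8 ± 27.8 to 0.494 ± 0.364 (−5.57 ± 0.45, adjusted p = 0.0042). Prdx6b (−5.23), 1700029F12Rik (−5.10), 4930544G11Rik (−5.01) and Gykl1 (−4.96) completed the 8 deepest.

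The rises at P18 were shallow. Loxl4 (chromosome 19, 42593982 to 42612813), a lysyl oxidase-like gene, rose from 0.505 ± 0.0833 to 1.61 ± 0.261 (1.06 ± 0.19, adjusted p = 0.0141). Ctcfl (chromosome 2, 173093609 to 173119525), the germ-cell paralogue of Ctcf, rose from 3.59 ± 0.103 to 6.67 ± 0.518 (0.81 ± 0.09, adjusted p = 0.00442). Nudt17 (0.80 ± 0.13, adjusted p = 0.00924) was also among the 8 largest. The others, Rcan3, Ankrd29, Zglp1, Ube2cbp and Cd59a, rose by 0.71 to 0.87, and each lost its call without at least 1 single library, Het replicate 2 in the case of Rcan3 and Ankrd29. For Zglp1, 90.09% of the 50-mers also occurred elsewhere in the annotated genes. Of 18786 genes, 1106 rose and 3232 fell, 33 and 1456 of them by at least 1 on the log2 scale.

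In the pachytene transcription programme of P18 testis 27 of 33 members fell and 1 rose (30 and 1 adjusted over the list alone), with a median of −1.87. Spata16, a gene of acrosome formation, fell by 4.85 ± 0.34 and Taf7l, an X-linked TFIID subunit gene, was the member that rose (0.32, a call that ended without Het replicate 2, KO replicate 2 or KO replicate 3). In the axoneme and cilium list 32 of 35 fell (35 adjusted over the list alone, median −2.22), among them Cfap206 from 48.2 to 1.98 (−4.18 ± 0.34) and Cfap52 (−3.95 ± 0.38). Of the piRNA pathway 18 of 24 fell (20 lower and 1 higher adjusted over the list alone, median −0.69), with Tdrd6, a chromatoid body protein gene, down from 36.7 to 1.22 (−4.29 ± 0.38) and Piwil1 from 106 to 16.5 (−2.58 ± 0.26). Of the round spermatid and acrosome list 10 of 13 fell (10 adjusted over the list alone, median −1.60), with Zpbp2, which binds the zona pellucida, down from 32.9 to 1.97 (−3.67 ± 0.40). Of the autosomal retrogenes of X-linked genes 11 of 12 fell (12 adjusted over the list alone, median −1.24), with Cetn1 from 54.1 to 1.46 (−4.69 ± 0.34) and Pgk2, the testis phosphoglycerate kinase, from 15.5 to 0.113 (−4.55 ± 0.43). The 5 lists passed as sets with an adjusted p of 1.84e-14, 2.41e-18, 4.79e-08, 5.12e-05 and 2.21e-08 in that order, and each with an adjusted p = 0.267 with an estimated correlation. In these same testes the Sertoli list lay higher in KO, with a median of 0.28.

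Lists of spermatogonia, meiotic entry, break formation, the chromosome axis, the G2 to metaphase I cell cycle and silenced sex chromosome genes had medians of −0.23 to 0.28 in P18 testis. Of the spermatogonial list 6 of 26 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.000922, and adjusted p = 0.267 with an estimated correlation). The members that fell were Dmrtb1, a regulator of the switch from mitosis to meiosis, from 63.0 to 19.3 (−1.63 ± 0.26), and Id4, a regulator of stem spermatogonia (−0.75 ± 0.08). Of the meiotic entry list 7 of 24 rose and 3 fell (9 and 4 adjusted over the list alone, median 0.22, adjusted p = 0.0201, and adjusted p = 0.267 with an estimated correlation). Gm4969, which encodes the STRA8 partner MEIOSIN, rose from 23.4 to 35.4 (0.59 ± 0.06). Break formation and strand exchange had 5 risen and 7 fallen members of 34 (6 and 7 adjusted over the list alone, median −0.04, adjusted p = 0.666). Zcwpw1, a reader of PRDM9 histone marks, rose by 0.53 ± 0.07, and Psmc3ip, a cofactor of strand exchange, fell by 1.05 ± 0.13. In the axis and synaptonemal complex list 6 of 20 fell (10 adjusted over the list alone, median −0.23, adjusted p = 0.0147, and adjusted p = 0.267 with an estimated correlation). Ccdc155, a telomere attachment protein gene also known as Kash5, fell from 40.9 to 24.0 (−0.76 ± 0.07). Of the G2 to metaphase I list 14 of 36 fell and 1 rose (16 and 3 adjusted over the list alone, median −0.18, adjusted p = 0.0293, and adjusted p = 0.482 with an estimated correlation). The meiotic cyclin gene Ccna1 fell from 10.4 to 0.370 (−3.46 ± 0.42). Sex chromosome genes silenced in pachytene rose in 22 of 41 cases and fell in 0 (28 and 0 adjusted over the list alone, median 0.28, adjusted p = 9.65e-11, and adjusted p = 0.267 with an estimated correlation). The X-linked RNA export gene Nxf2 was among them (0.40 ± 0.05).

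Somatic marker lists also lay higher in KO testes at P18. Of 25 Sertoli genes 8 rose (23 adjusted over the list alone, median 0.28, adjusted p = 1.17e-07, and adjusted p = 0.267 with an estimated correlation). Of 16 macrophage and leukocyte genes 8 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.45, adjusted p = 0.000414, and adjusted p = 0.267 with an estimated correlation). Here the lysozyme gene Lyz2 rose by 0.66, and the Fc receptor gene Fcgr3 fell from 12.1 to 2.91 (−1.82 ± 0.25). Leydig genes passed as a set (1 of 13 higher, 0 adjusted over the list alone, median 0.31, adjusted p = 0.0293, and adjusted p = 0.385 with an estimated correlation). So did peritubular myoid (0 of 10, median 0.25, adjusted p = 0.0384) and endothelial genes (0 of 7, median 0.29, adjusted p = 0.0499). With an estimated correlation the latter had an adjusted p = 0.528 and 0.267. Erythroid genes did not pass (0 of 5, median 0.70, adjusted p = 0.109). The p53 targets (4 of 22 higher, 1 lower, 6 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.024) and interferon-stimulated genes (2 of 16 higher, 0 adjusted over the list alone, median 0.23, adjusted p = 0.00137) passed as sets. Each had an adjusted p = 0.267 with an estimated correlation. Mitochondrially encoded genes passed (0 of 13, median 0.24, adjusted p = 0.00156, and adjusted p = 0.43 with an estimated correlation). Cytoplasmic ribosomal proteins did as well (3 of 50 higher, 1 lower, 0 adjusted over the list alone, median 0.06, adjusted p = 0.00391, and adjusted p = 0.474 with an estimated correlation). Immediate-early and heat-shock genes did not (1 of 21 higher, 2 lower, 0 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.0882), although the heat-shock gene Hsp90aa1 (−0.74) fell.

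The balance of rises and falls in P18 testis differed between settings. Of the called genes 25.5% were higher in KO, against 28% with median-of-ratios scaling and 46.4% on the values as deposited, which shifted the median gene by 0.099. With voom, which also changed the test and the genes tested, it was 36.8%. Without Het replicate 1, 2 or 3 the counts were 452, 115 and 1036 higher and 2098, 1414 and 3230 lower. Without KO replicate 1, 2 or 3 they were 235, 78 and 105 higher and 1696, 1498 and 1594 lower. The myoid and endothelial set calls ended without Het replicate 1, Het replicate 3, KO replicate 2 or KO replicate 3, and that of the Leydig list without Het replicate 2, KO replicate 1 or KO replicate 3. The lists for p53 targets (Het replicate 1), meiotic entry and ribosomal proteins (Het replicate 2) and G2 to metaphase I (KO replicate 1) lost theirs without 1 library each. Over these fits the adjusted p was 0.0509 to 0.136. With voom the calls of Prdx6b, Gykl1, Ccna1 and Pgk2 ended (adjusted p = 0.0606, 0.0757, 0.0563 and 0.0789), although their differences were larger there (−7.77, −7.885, −4.54 and −6.89). The size of these 4 falls depended on the pseudocount and was larger with 0.1 and smaller with 1. In 1 fit over all 18 libraries the Leydig, myoid and G2 to metaphase I set calls ended (adjusted p = 0.277, 0.308 and 0.0528). Under a stricter filter the myoid, endothelial and p53 calls ended (adjusted p = 0.0753, 0.0581 and 0.0534). The endothelial call also ended with median-of-ratios scaling (adjusted p = 0.0522), and as deposited it and the Leydig call ended (adjusted p = 0.0738 and 0.0621).

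In isolated P18 spermatocytes transcripts of late spermatocytes and of sperm structures were also far lower in KO than in Het. This comparison asked for the differences within the spermatocyte fraction. Fbp1 (chromosome 13, 62864753 to 62888282), an enzyme gene of gluconeogenesis, fell from 141 ± 69.5 to 0.947 ± 0.805 (−6.64 ± 0.44, adjusted p = 0.000122). Adam3 fell from 71.4 ± 46.1 to 0.321 ± 0.198 (−6.30 ± 0.41, adjusted p = 0.000122), and Pabpc2, a poly(A)-binding protein gene of germ cells, fell from 90.6 ± 51 to 0.598 (−6.28). Cmtm2a fell from 97.1 ± 54 to 0.48 (−6.55 ± 0.38), with 39.86% of its 50-mers shared with other genes, and 1700029F12Rik (−6.51), 1700123L14Rik (−6.47), Pebp4 (−6.38) and Plaat5 (−6.27) completed the 8 deepest falls. Sohlh2 (chromosome 3, 55182028 to 55209957), a transcription factor gene of differentiating spermatogonia, rose from 27.4 ± 1.5 to 59.2 ± 4.39 (1.10 ± 0.10, adjusted p = 0.000265).

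Other rises in KO spermatocytes were those of Loxl4 (from 0.573 ± 0.166 to 2.16 ± 0.392, 1.31 ± 0.21, adjusted p = 0.00347) and of Plau, the urokinase gene (chromosome 14, 20836660 to 20843385; 1.24 ± 0.24, adjusted p = 0.00659). The next were Wfs1 (1.13 ± 0.17), Tcf7l2 (1.07), Ajuba (0.97) and Pth1r (0.96). Mnd1, a cofactor of meiotic strand exchange, rose from 11.4 to 23.2 (0.99 ± 0.13, adjusted p = 0.00113), with 38.74% of its 50-mers shared with other genes. Of 15960 genes, 1492 rose and 4036 fell, 64 and 2278 of them by at least 1 on the log2 scale.

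In the axoneme and cilium list of spermatocytes 34 of 36 fell (35 adjusted over the list alone, median −3.15, adjusted p = 4.19e-17, and adjusted p = 0.418 with an estimated correlation), with Cfap206 down from 84.7 to 0.786 (−5.98 ± 0.35) and Cfap52 from 31.8 to 0.190 (−5.47 ± 0.29). In the pachytene transcription programme 27 of 33 fell (27 lower and 1 higher adjusted over the list alone, median −2.35, adjusted p = 3.89e-10, and adjusted p = 0.418 with an estimated correlation), with Crisp2 down from 137 to 1.29 (−6.24 ± 0.38). Of the round spermatid and acrosome list 13 of 18 fell (13 adjusted over the list alone, median −1.51, adjusted p = 0.000566, and adjusted p = 0.418 with an estimated correlation), among them Dkkl1 from 135 to 3.89 (−4.84 ± 0.32) and the acrosin gene Acr from 29.2 to 0.529 (−4.75 ± 0.34). Of the autosomal retrogenes 10 of 12 fell (11 adjusted over the list alone, median −1.41, adjusted p = 4.77e-05, and adjusted p = 0.418 with an estimated correlation), among them Cetn1 (−6.14 ± 0.43) and Fam50b (−5.38 ± 0.36). Of the piRNA pathway 14 of 25 fell and 1 rose (17 and 3 adjusted over the list alone, median −0.75, adjusted p = 0.00082, and adjusted p = 0.506 with an estimated correlation). Piwil1 fell from 232 ± 77.4 to 9.96 ± 2.35 (−4.45 ± 0.25) and Tdrd6 from 90.3 to 1.41 (−5.49 ± 0.37). Fkbp6, an immunophilin gene of the pathway, rose by 0.38.

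Part of the spermatogonial and meiotic entry genes rose in KO spermatocytes. Of the spermatogonial list 11 of 26 rose and 1 fell (12 and 2 adjusted over the list alone, median 0.48, adjusted p = 4.77e-05, and adjusted p = 0.472 with an estimated correlation). Dmrt1, a regulator of germ-cell mitosis, rose from 71.2 to 115 (0.69 ± 0.12), and Id4 fell from 22.0 to 5.79 (−1.82 ± 0.21). Of the meiotic entry list 13 of 24 rose (13 higher and 1 lower adjusted over the list alone, median 0.38, adjusted p = 0.000302, and adjusted p = 0.418 with an estimated correlation). The replicative helicase genes Mcm2 (0.78 ± 0.11) and Mcm4 (0.69 ± 0.10) were among them. Break formation and strand exchange had 5 risen and 9 fallen members of 34 (5 and 9 adjusted over the list alone), and its median was −0.07 while the set test pointed up (adjusted p = 0.763). Spo11, the gene of the meiotic break enzyme, fell from 24.5 to 9.10 (−1.45 ± 0.26). The axis and synaptonemal complex list had 2 risen and 5 fallen members of 20 (2 and 6 adjusted over the list alone, median −0.07, adjusted p = 0.763). Syce1, of the central element, fell from 141 to 63.9 (−1.10 ± 0.19). The G2 to metaphase I list had 10 risen and 12 fallen members of 36 (12 and 13 adjusted over the list alone), with a median of 0.07, a mean of −0.27 and an adjusted p of 0.295. Wee1, an inhibitor kinase of mitotic entry, rose (0.66 ± 0.10), while Ccna1 fell (−2.94 ± 0.46) and Meikin, a meiosis I kinetochore gene, fell from 14.1 to 3.07 (−2.01 ± 0.22). Sex chromosome genes silenced in pachytene rose in 7 of 39 cases (3 adjusted over the list alone, median 0.29, adjusted p = 2.4e-05, and adjusted p = 0.534 with an estimated correlation). Uba1 (X chromosome, 20658326 to 20683179), a ubiquitin-activating enzyme gene, rose from 44.2 to 66.6 (0.59 ± 0.12).

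Sertoli markers did not lie higher in KO spermatocytes: 0 of 22 passed, with a median of −0.49 (adjusted p = 0.388). Peritubular myoid genes (0 of 10, median −0.12, adjusted p = 0.763) and Leydig genes (2 of 4 lower, 2 adjusted over the list alone, median −0.35, adjusted p = 0.323) did not pass as sets. Neither did endothelial genes (1 of 2 higher, 1 adjusted over the list alone, median 0.45, adjusted p = 0.123), and the erythroid list was not tested. Of 11 macrophage and leukocyte genes 3 rose and 1 fell (the same adjusted over the list alone, median 0.58, adjusted p = 0.0352, and adjusted p = 0.418 with an estimated correlation). The complement gene C1qa rose from 0.858 to 2.61 (1.26), and Fcgr3 fell from 14.8 to 0.526 (−3.86 ± 0.25). All 7 mitochondrially encoded genes tested rose (7 adjusted over the list alone, median 0.47, adjusted p = 0.000713, and adjusted p = 0.472 with an estimated correlation). The complex I gene mt-Nd1 rose from 2034 to 2977 (0.55). Of the p53 targets 5 of 21 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.00118, and adjusted p = 0.418 with an estimated correlation). Bax, a pro-apoptotic gene, and Ccng1 rose by 0.61 and 0.62. Interferon-stimulated genes passed as a set (2 of 9 higher, 1 lower, 3 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.0303, and adjusted p = 0.506 with an estimated correlation). So did cytoplasmic ribosomal proteins (4 of 50 higher, 2 lower, 0 adjusted over the list alone, median 0.09, adjusted p = 0.00286, and adjusted p = 0.586 with an estimated correlation). Immediate-early and heat-shock genes did not (2 of 23 higher, 2 lower, the same adjusted over the list alone, median 0.13, adjusted p = 0.0866). The macrophage call ended without KO replicate 1, 2 or 3 (adjusted p = 0.325, 0.365 and 0.374). The interferon call ended without Het replicate 1, Het replicate 3 or KO replicate 1 (adjusted p = 0.07, 0.0624 and 0.0967). The macrophage call also ended with median-of-ratios scaling (adjusted p = 0.0737), in 1 fit over all 18 libraries (adjusted p = 0.362) and as deposited (adjusted p = 0.183). The interferon call also ended under a stricter filter (adjusted p = 0.0632), in 1 fit (adjusted p = 0.126) and as deposited (adjusted p = 0.104). The mitochondrial call ended without a filter (adjusted p = 0.0841).

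The balance in spermatocytes depended on the rescaling: 27% of the called genes were higher in KO, against 38.7% with median-of-ratios scaling and 54.3% as deposited. It was 42.9% with voom and 53.1% in 1 fit over all 18 libraries, which changed the genes tested and the variance as well. The median gene shifted by 0.222 as deposited. Fewer genes rose without KO replicate 2 (664) or KO replicate 3 (473), and fewer fell without Het replicate 1 (2358). Het replicate 3 had the highest deposited values of Adam3 (106.3, against 39.94 and 45.72) and Piwil1 (272.3, against 187.1 and 172.2). The KO libraries had at most 0.5419 and 13.82 of these genes.

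**Figure D2:**
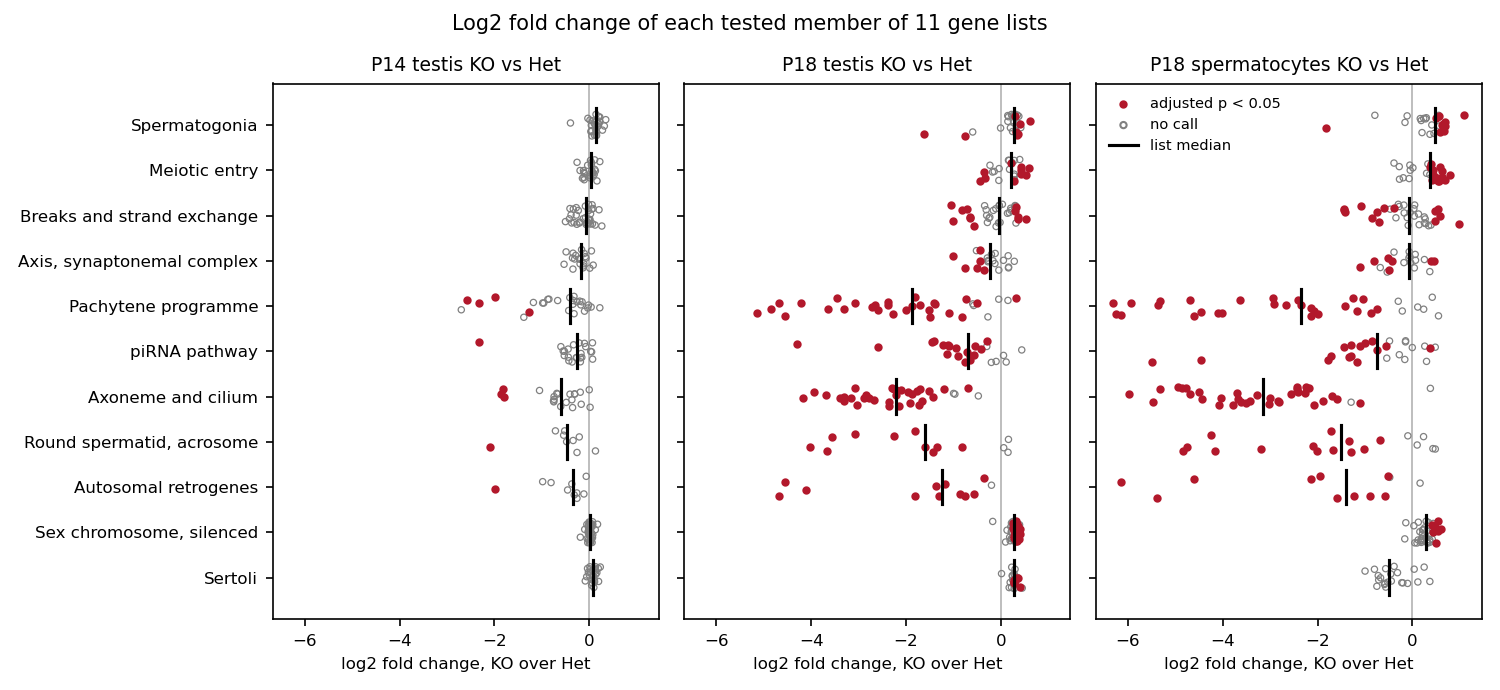
Log2 fold change (x axis, KO over Het) of each tested member of 11 gene lists in the 3 sets of libraries; red points had an adjusted p under 0.05, open points had no call, and the black bar is the list median. The medians of the axoneme and cilium list were −0.60, −2.22 and −3.15, and those of the spermatogonial list 0.14, 0.27 and 0.48, from left to right.

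Whether the genotype difference itself changed with age was tested as an interaction in the 12 testis libraries. As in all comparisons across ages, many genes of chromosomes 10 and 12 to 19 were left out. The largest lower differences at P18 included genes near the detection limit at P14. For such genes the 0.5 added before the log bounds the fall that can be recorded at P14. The test therefore cannot tell a change of the genotype effect with age from this bound. Hspb9 stood at 0.544 in Het and 0.361 in KO at P14 and at 58.8 and 0.904 at P18 (interaction −5.04 ± 0.44, adjusted p = 0.00245, n = 3 per group). Adam3 stood at 0.348 and 0.0576 at P14 and at 37.4 and 0.519 at P18 (−4.47 ± 0.45, adjusted p = 0.00245). Ctcfl, at 4.57 in Het and 5.43 in KO at P14 and at 6.10 in KO at P18, moved the other way (0.58 ± 0.13, adjusted p = 0.0261). Its call ended without any 1 of P14 Het replicates 1 and 3, P18 Het replicate 2 and P18 KO replicates 2 and 3 (adjusted p = 0.0567 to 0.0827). Neither Zfp541 (−0.22 ± 0.23, adjusted p = 0.625) nor Kctd19 (−0.63, adjusted p = 0.227) passed.

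Of 16274 genes, 57 had a higher and 917 a lower difference at P18 (8 and 631 by at least 1). The axoneme and cilium list had 16 lower of 24 (22 adjusted over the list alone, median −1.59, adjusted p = 1.99e-15, and adjusted p = 0.408 with an estimated correlation). The pachytene programme had 12 of 25 (14 lower and 1 higher adjusted over the list alone, median −0.86, adjusted p = 8.22e-09, and adjusted p = 0.408 with an estimated correlation). The round spermatid list had 4 of 10 (6 adjusted over the list alone, median −1.09, adjusted p = 0.00117, and adjusted p = 0.408 with an estimated correlation). The autosomal retrogenes had 2 of 8 (6, median −0.67, adjusted p = 0.00227, and adjusted p = 0.408 with an estimated correlation). The piRNA pathway had 4 of 18 (7, median −0.31, adjusted p = 0.00117, and adjusted p = 0.488 with an estimated correlation). Spata16 (−3.41), Ccna1 (−3.17), Tdrd6 (−3.25) and Zpbp2 (−2.92) were members with a lower difference at P18. The sex chromosome list had 2 higher of 38 (8 adjusted over the list alone, median 0.25, adjusted p = 6.77e-11, and adjusted p = 0.408 with an estimated correlation). Meiotic entry (1 higher of 20, median 0.17), Sertoli (0 of 21, 0.17), macrophage (0 of 11, 0.52), p53 (0 of 16, 0.17), interferon (0 of 14, 0.24) and mitochondrially encoded genes (0 of 13, 0.27) also passed as sets. Their adjusted p was 9.07e-05 to 0.0237, and adjusted p = 0.408 to 0.522 with an estimated correlation, and 11 lists did not pass. With voom 4 and 126 genes passed, and the calls of Hspb9, Adam3, Ctcfl, Spata16, Ccna1, Tdrd6 and Zpbp2 ended (differences of −5.34, −3.47, 0.64, −1.81, −3.95, −2.88 and −2.87). Without P18 Het replicate 2 the counts were 5 and 30 and the call of Zpbp2 ended (adjusted p = 0.0522). Without P18 Het replicate 3 they were 230 and 1535, and without any other single library they were 15 to 37 and 487 to 762.

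A second interaction asked whether the genotype difference at P18 differed between isolated spermatocytes and whole testis. Efhd1, a mitochondrial calcium-binding protein gene, stood at 83.1 in Het and 59.5 in KO testis but at 89.8 and 2.34 in spermatocytes (interaction −4.48 ± 0.44, adjusted p = 0.00288, n = 3 per group). Slc47a2, an organic cation exporter gene, stood at 60.3 and 60.7 in testis and at 40.4 and 2.59 in spermatocytes (−3.81 ± 0.46, adjusted p = 0.00818). Rnf144b, a ubiquitin ligase gene, stood at 15.8 and 14.2 in testis and at 10.9 and 0.652 in spermatocytes (−3.08 ± 0.33, adjusted p = 0.00348). Cerk, the ceramide kinase gene, stood at 36.4 and 40.4 in testis and at 13.3 and 2.08 in spermatocytes (−2.55, adjusted p = 0.00818). Zfp541 did not pass (−0.55 ± 0.25, adjusted p = 0.324), nor did any of the 6 partner genes.

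Of 19979 genes, 13 had a higher and 247 a lower difference in spermatocytes (11 and 192 by at least 1), with a median over all genes of −0.105. That median turned to 0.051 without spermatocyte Het replicate 2, where the counts at an unadjusted p under 0.05 were 2431 higher and 1742 lower, against 438 and 2654. It also turned as deposited (0.042). The axoneme and cilium list lay lower (0 of 36 called, 17 lower and 1 higher adjusted over the list alone, median −1.11, adjusted p = 4.9e-08, and adjusted p = 0.698 with an estimated correlation). So did the pachytene programme (1 of 33 lower, 8 lower and 1 higher adjusted over the list alone, median −0.46, adjusted p = 0.0175, and adjusted p = 0.955 with an estimated correlation). Sertoli markers also lay lower (0 of 25, median −0.73, adjusted p = 2.73e-05, and adjusted p = 0.698 with an estimated correlation). The G2 to metaphase I list lay higher (0 of 36 called, 4 higher adjusted over the list alone, median 0.17, adjusted p = 1.53e-06). It passed with an estimated correlation too (adjusted p = 0.0167). Spermatogonial (median 0.20, adjusted p = 0.000364), meiotic entry (0.09, adjusted p = 0.000858) and p53 lists (0.13, adjusted p = 0.0132) lay higher, each with an adjusted p = 0.698 with an estimated correlation, and 16 lists did not pass. Without testis Het replicate 2 the counts were 0 and 20, and over all fits without 1 library the higher count was 0 to 22. The lower count was 154 and 57 without testis Het replicates 1 and 3, and 26, 21 and 21 without testis KO replicates 1, 2 and 3. It was 76, 37 and 38 without spermatocyte Het replicate 2, KO replicate 1 and KO replicate 2, and 336 without spermatocyte Het replicate 3. As deposited, 58 genes had a higher difference, and the median gene moved by 0.158 here and by 0.108 in the interaction with age.

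Between P14 and P18, Het testes gained transcripts of late spermatocytes. Hspb9 rose from 0.544 to 58.8 (5.73 ± 0.31, adjusted p = 5.38e-08, n = 3 and 3) and Adam3 from 0.348 to 37.4 (5.34 ± 0.32, adjusted p = 1.14e-07). Cmtm2b rose from 0.302 to 47.0 (5.79 ± 0.35), and 1700123L14Rik (5.49) and Cmtm2a (5.11) completed the 5 largest rises. Zfp541 rose from 9.44 to 23.0 (1.23 ± 0.17, adjusted p = 8.42e-05) and Kctd19 by 1.84 ± 0.20 (adjusted p = 2e-05), and Piwil1 rose from 14.8 to 96.7 (2.63 ± 0.27). In KO testes Zfp541 rose from 4.44 to 9.36 (1.01 ± 0.17, adjusted p = 0.000584), Kctd19 by 1.21 and Piwil1 by 2.39. Ldhc, the testis lactate dehydrogenase gene, rose from 3.70 to 44.3 in KO (3.48 ± 0.37, adjusted p = 1.99e-05) and from 26.7 to 404 in Het. Aqp8, a water channel gene, rose from 1.32 to 16.1 in KO (3.26 ± 0.30, adjusted p = 6.32e-06).

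In Het testes all 24 axoneme and cilium genes tested rose with age (24 adjusted over the list alone, median 2.33, adjusted p = 2.22e-09, and adjusted p = 0.516 with an estimated correlation). Of 25 pachytene programme genes 20 rose and 3 fell (21 and 3 adjusted over the list alone, median 2.05, adjusted p = 5.71e-06, and adjusted p = 0.516 with an estimated correlation). Of 18 piRNA genes 15 rose (15, median 1.02, adjusted p = 2.94e-05), of 10 round spermatid genes 9 (9, median 1.57, adjusted p = 0.000332) and of 17 axis genes 9 (9, median 0.42, adjusted p = 0.00865), each with an adjusted p = 0.516 with an estimated correlation. Sex chromosome genes fell in 34 of 38 cases (36 adjusted over the list alone, median −0.54, adjusted p = 3.54e-07, and adjusted p = 0.516 with an estimated correlation), among them Usp9x from 44.6 to 17.6 (−1.31). Spermatogonial genes fell in 15 of 24 cases and rose in 1 (15 and 1, median −0.48, adjusted p = 0.0182, and adjusted p = 0.516 with an estimated correlation). Ribosomal protein genes fell in 27 of 39 cases and rose in 3 (27 and 3, median −0.24, adjusted p = 0.00104), mitochondrially encoded genes fell in 12 of 13 (12, median −1.42, adjusted p = 4e-06), and autosomal retrogenes rose in 5 of 8 and fell in 1 (6 and 1, median 1.18, adjusted p = 0.0265), each with an adjusted p = 0.516 with an estimated correlation. Sertoli genes fell in 13 of 21 cases and rose in 1 (13 and 1, median −0.27, adjusted p = 0.0265, and adjusted p = 0.574 with an estimated correlation). In KO testes the axoneme list had 14 risen of 24 (17 adjusted over the list alone, median 0.73, adjusted p = 0.000157, and adjusted p = 0.586 with an estimated correlation). The pachytene programme had 12 risen and 3 fallen of 25 (13 and 3 adjusted over the list alone, median 0.56, adjusted p = 0.00324, and adjusted p = 0.586 with an estimated correlation). The piRNA pathway had 10 risen of 18 (12, median 0.48, adjusted p = 0.000256, and adjusted p = 0.586 with an estimated correlation). The sex chromosome list had 25 fallen of 38 (29 lower and 2 higher, median −0.33, adjusted p = 0.000256, and adjusted p = 0.586 with an estimated correlation). Leydig genes rose in 4 of 9 cases (4, median 0.70, adjusted p = 0.0329) and macrophage genes in 3 of 11 (2, median 0.57, adjusted p = 0.0222), each with an adjusted p = 0.586 with an estimated correlation. Break formation, axis, round spermatid, spermatogonial, ribosomal protein and mitochondrially encoded lists also passed in KO (medians 0.12, 0.28, 0.65, −0.41, −0.21 and −1.20, adjusted p = 0.000124 to 0.0273). Each of these had an adjusted p = 0.586 with an estimated correlation. In Het 4786 genes rose and 5289 fell of 16274 (1867 and 2003 by at least 1), and in KO 2941 rose and 4194 fell (753 and 1994). The largest falls with age in both genotypes were transcripts with near-identical copies, such as mt-Co3 (−7.73 in Het, 100% of its 50-mers shared) and Rpl10-ps3 (−7.61 in Het, 95.41% shared). Gm21704 was listed at 0 in all P18 testis libraries against 88.4 at P14 in Het. Age and any difference in library handling between the ages cannot be separated in these libraries. As deposited 65% of the called genes in Het and 77% in KO rose, against 47.5% and 41.2% after rescaling, with shifts of the median gene by 0.181 and 0.287.

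Isolated Het spermatocytes differed from Het testis at P18 by the loss of somatic transcripts. Insl3, a Leydig cell hormone gene, fell from 95.9 to 0.602 (−6.51 ± 0.32, adjusted p = 8.75e-08, n = 3 and 3), and Cst12, a Sertoli cystatin gene, from 287 to 10.2 (−4.78 ± 0.26, adjusted p = 1.62e-07). The immediate-early genes Fosb, from 0.423 to 29.4 (4.93 ± 0.39, adjusted p = 1.78e-06), and Fos, from 1.74 to 54.0 (4.54 ± 0.34, adjusted p = 1.27e-06), rose most, followed by Egr1 (2.66), Atf3 (2.64) and Nr4a1 (2.58). Zfp541 (0.86 ± 0.18, adjusted p = 0.0017) and Piwil1 (1.25) were higher in spermatocytes. Of 25 Sertoli genes 24 fell and 1 rose (24 and 1 adjusted over the list alone, median −3.78, adjusted p = 2.68e-12, and adjusted p = 0.257 with an estimated correlation). All 13 Leydig genes fell (13, median −2.65, adjusted p = 3.01e-07, and adjusted p = 0.155 with an estimated correlation). Macrophage genes fell in 13 of 17 cases and rose in 1 (13 and 1, median −1.48, adjusted p = 0.000325, and adjusted p = 0.257 with an estimated correlation). Myoid genes did not pass (0 of 10, median 0.02, adjusted p = 0.883). The G2 to metaphase I list had 28 risen of 36 (28 adjusted over the list alone, median 0.75, adjusted p = 7.38e-09, and adjusted p = 0.00587 with an estimated correlation). Break formation had 27 risen and 1 fallen of 34 (28 and 1, median 0.67, adjusted p = 4.28e-08, and adjusted p = 0.257 with an estimated correlation). Immediate-early and heat-shock genes rose in 17 of 24 cases and fell in 2 (17 and 2, median 1.62, adjusted p = 7.2e-05, and adjusted p = 0.337 with an estimated correlation). Of 19979 genes 5414 were higher and 6349 lower in spermatocytes (721 and 3922 by at least 1), a share of 46% higher against 34.7% as deposited, where the median gene moved by −0.153. The fraction is confounded with cell isolation and with the unit of the deposited values.

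How the genes that change with age in Het testis differed between KO and Het spermatocytes was compared in sets taken from the contrast of P18 with P14 Het testis. The fit behind that contrast held 12 libraries, the KO testes among them. Of the genes that rose with age in Het testis, 4327 were tested in spermatocytes, and 2494 of them (57.6%) were lower and 67 (1.55%) higher in KO, with a median of −0.65 (camera p = 1.69e-35, and p = 0.0966 with an estimated correlation). That median was −0.42 without Het replicate 3 and also as deposited. Of the genes that fell with age, 3194 were tested, and 736 (23%) were higher and 75 (2.35%) lower in KO, with a median of 0.25 (camera p = 2.44e-24, and p = 0.0597 with an estimated correlation). Of 4406 genes with no call for age, 331 were higher and 383 lower, with a median of 0.04.

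The genes called in the 3 comparisons of KO with Het overlapped. All 29 genes that fell at P14 and were tested in P18 testis fell there too, against 4.37 by chance (Fisher's exact test, p = 1.29e-24), and 28 of 28 fell in spermatocytes, against 6.25 by chance (p = 5.24e-19). Between P18 testis and spermatocytes 2659 genes fell in both, of 3102 and 3909, against 797 by chance, and 375 rose in both, of 980 and 1433, against 92.3 by chance (Fisher's exact test, p = 4.35e-145). Opposite directions were seen for 4 and 3 genes, against 252 and 292 by chance. With a change of at least 1 on the log2 scale, 1309 fell in both and 1 rose in both. Genes are not independent replicates, so the Fisher p values and the counts by chance do not measure how well the libraries replicate each other.

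X-linked genes lay higher in KO at P18. In P18 testis their median was 0.28 against 0.01 for autosomal genes, with 139 of 667 higher and 5 lower (camera p = 8.08e-20, and p = 0.0957 with an estimated correlation). Somatic lists lay as high in the same testes, with medians of 0.28 (Sertoli), 0.31 (Leydig) and 0.45 (macrophage). In spermatocytes it was 0.30 against −0.07, with 77 of 510 higher and 3 lower (camera p = 5.13e-14, and p = 0.289 with an estimated correlation), and it was 0.19 without Het replicate 3, 0.12 without a filter and 0.51 as deposited. At P14 the median was 0.03 against 0.01, with 0 of 791 called by limma (camera p = 0.00516, and p = 0.245 with an estimated correlation), and this call ended without Het replicate 1 or KO replicate 2 (p = 0.143 in both). The difference between P18 and P14 testis was itself tested, with a median of 0.20 (camera p = 5.95e-14, and p = 0.0307 with an estimated correlation). That between spermatocytes and testis was −0.05 against −0.11 for autosomal genes (camera p = 0.0387, and p = 0.699 with an estimated correlation). In Het testes X-linked genes fell with age, 590 of 828 lower and 26 higher, with a median of −0.52 (camera p = 2.29e-18, and p = 0.0158 with an estimated correlation). In KO testes 439 were lower and 42 higher, with a median of −0.30 (camera p = 5.11e-11, and p = 0.0512 with an estimated correlation). Y-linked genes had a median of 0.23 in P18 testis, with 3 of 15 higher (camera p = 0.00387, and p = 0.282 with an estimated correlation). In spermatocytes it was 0.15 over 9 genes, 1 of them higher, and the set did not pass.

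**Figure D3:**
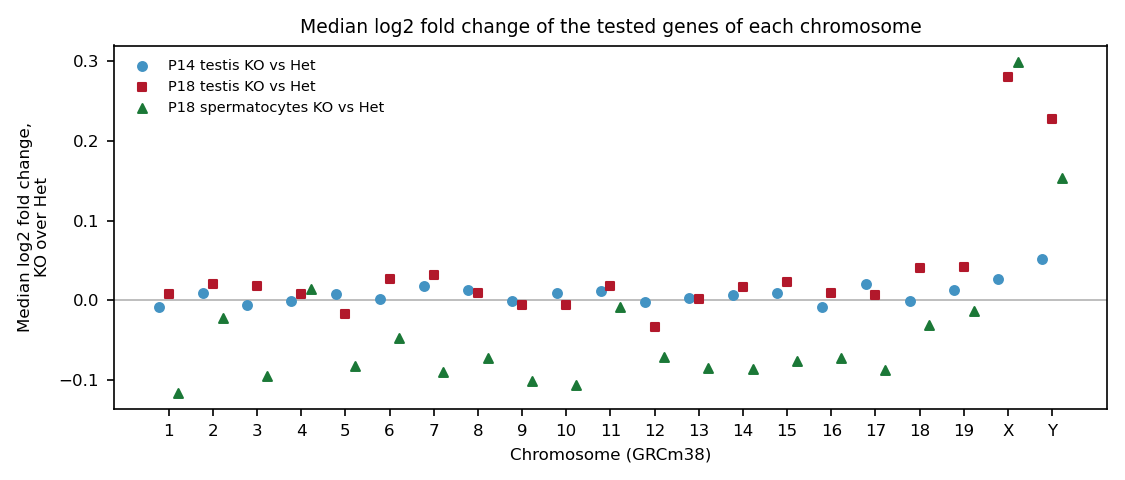
Median log2 fold change (y axis, KO over Het) of the tested genes of each chromosome (x axis) in P14 testis (circles), P18 testis (squares) and P18 spermatocytes (triangles). Of the chromosomes plotted, 1 to 19, X and Y, the X chromosome had the highest median at P18, 0.28 in testis and 0.30 in spermatocytes, and lay at 0.03 at P14. The mitochondrial genome is not plotted (median 0.18 and 0.46 at P18, with 1 of 36 and 13 of 26 higher).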

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

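The tests of the X-linked set against somatic RNA, of near-identical copies against age, and all 3 tests of the unequal falls were chosen only after the result was seen.

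The genotype difference differed between the ages in 57 genes with a higher and 917 with a lower difference at P18, tested as an interaction. The largest higher differences were those of Ctcfl (0.582), Rcan3 (0.559), Gnb5 (0.535), Lrch2 (0.506), Six5 (0.488), Gm4969 (0.475), Zcwpw1 (0.47) and Anp32a (0.467), and each of these 8 calls ended without at least 1 single library. The largest lower differences were those of Hspb9 (−5.04), 1700123L14Rik (−4.76), Prdx6b (−4.642), Adam3 (−4.473), Qrich2 (−4.395), CK137956 (−4.209), Pbp2 (−4.149) and Ppp3r2 (−4.098). None of these 8 lost its call without a single library, while all lost it with voom (differences of −5.341 to −3.173 there). Hspb9 and Adam3 lay near the detection limit at P14, where the added 0.5 bounds the fall that can be recorded. For such genes the kept calls do not show that the genotype effect changed with age. Lists that differed were axoneme and cilium (median −1.593), round spermatid (−1.089), pachytene programme (−0.859), autosomal retrogenes (−0.666), piRNA pathway (−0.309), meiotic entry (0.166), p53 targets (0.165), Sertoli (0.172), interferon-stimulated (0.237), sex chromosome genes (0.247), mitochondrially encoded (0.272) and macrophage (0.517), all with the preset correlation only. X-linked genes as a set differed by a median of 0.202. Of 100 splits drawn for this interaction, the real one included, 12 called as many genes as the real 974, the highest 3801, so chance is not excluded by this count. All 12 kept the genotypes of the P18 libraries together, so they hold the genotype effect at P18 itself and are no plain draws of chance, and the highest swapped the genotypes of 1 set, which adds both effects. The structure of the samples behind these counts is that of genotype, and the 76 splits that kept neither genotype set reached at most 3. Those 76 splits place the genotype difference in the spread, which lowers their counts, so they give no measure of chance either.

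The genotype difference also differed between spermatocytes and testis at P18, in 13 genes with a higher and 247 with a lower difference. The genes were Tmem59l (0.562), Efhd1 (−4.484), Slc47a2 (−3.809), Rnf144b (−3.077), Gm49661 (−2.88, with 100% of its 50-mers shared), Gramd1b (−2.616), Dusp15 (−2.567), Cerk (−2.546) and H2bc21 (−2.425). The calls of Tmem59l, Gm49661, Gramd1b, Dusp15 and H2bc21 ended without at least 1 single library. Lists that differed were axoneme and cilium (−1.106), Sertoli (−0.73), pachytene programme (−0.458), meiotic entry (0.09), p53 targets (0.126), G2 to metaphase I (0.173) and spermatogonia (0.195), of which the G2 to metaphase I list also passed with an estimated correlation. X-linked genes as a set had a median of −0.051. Of 100 splits, 3 called as many genes as the real 260, the highest 9429, which swapped the genotypes of 1 set and so adds both genotype effects; the other kept the genotypes of the spermatocytes, so the structure of the samples behind both is that of genotype. As above, the share and the 76 splits keeping neither set (at most 2) do not measure chance.

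X-linked genes lay higher in KO at P18 than autosomal genes. Reads shared between copies are argued against, since genes with under 5% shared 50-mers kept 93.7% of the excess in testis and 97.8% in spermatocytes. RNA of Sertoli cells is argued against as the whole cause in spermatocytes, where the Sertoli list had a median of −0.487, while the macrophage list lay higher in KO (median 0.578, adjusted p = 0.0352, and adjusted p = 0.418 with an estimated correlation, a call that ended without any 1 KO replicate, with Fcgr3 lower) and RNA of other somatic cells stays open there, as does somatic RNA in P18 testis, where the Sertoli (0.276) and macrophage lists (0.449) lay as high as X-linked genes (0.28). Fewer cells past the stage at which X-linked transcripts fall stays open: the median of 296 X-linked genes was 0.315, and 1000 draws of autosomal genes matched on age effect and level gave a median of 0.276, with the central 95% of draws between 0.241 and 0.314. The X-linked median passed that range by less than its bootstrap SE of 0.014, a comparison with the spread made after the value was seen, and an effect of the genotype on X-linked genes themselves also stays open as untested.

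Genes with near-identical copies were lower in P18 than in P14 testis and lower in spermatocytes than in P18 testis. Shared reads counted differently in the sets of libraries may account for this. In Het, 213 genes with at least 90% shared 50-mers differed with age in median by −1.34 from 5542 with under 1% (KO −1.43). Age cannot be told apart from the set of libraries, as all P14 libraries are of 1 set. At 1 age (P18, Het), the difference between spermatocytes and testis was −0.38, with mt-Co2, mt-Co3 and mt-Nd4l (100% shared) at −6.02, −5.71 and −4.92. The gene mt-Atp8 (0% shared) fell by 6.85 with age, but copies outside annotated genes were not counted.

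Genes that rise with age fell in KO spermatocytes by unequal folds. Scaling of the libraries is argued against, since the median of 175 strongly age-induced genes was −4.69 in the results and −4.508 at its highest over 3 scalings. A larger share of somatic RNA is argued against, since it would lower all spermatocyte transcripts alike, while meiotic entry genes had quartiles of −0.048 and 0.549, 4406 genes without a call for age a median of 0.038 and the axis list one of −0.07; the upper quartile of the Sertoli list was −0.207, and only the macrophage list (median 0.578, adjusted p = 0.418 with an estimated correlation) passed as higher among somatic lists, with the preset correlation. Loss of 1 cell class by 1 proportion stays open: at a fitted 1.86% of the Het level, 26.3% of these genes (46 of 175) lay over 2 standard errors away, 29 with a smaller and 17 with a larger fall, and the test bounds neither expression of these genes in other cells nor error in the smallest KO values. The biological difference between the genotypes stays open as untested beyond this.

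For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real counts were 32 at P14 (highest other 3), 4338 in P18 testis (0) and 5528 in spermatocytes (0), and those of age in Het, age in KO and fraction had a highest other of 0, 1 and 1; in each, 1 of 10 splits gave as many genes. The excess of the X-linked median was 0.021 at P14, where 6 of 10 splits were as large (highest other 0.059), 0.268 in P18 testis (highest other 0.166) and 0.366 in spermatocytes (highest other 0.303). The age sets had medians of −0.646 and 0.251 against a highest other size of 0.385 and 0.149.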

How the results depend on the processing

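The settings as deposited, voom, pseudocounts and the age sets limited to genes with under 5% shared 50-mers were chosen only after the result was seen. Of the counts and sets under other settings 272 were within the same bounds, 110 moved and 7 lost the call; of the lists, run so in the 3 comparisons of KO with Het only, 555 kept and 90 lost theirs, 43 of these by the estimated correlation; of the named genes 6893 were the same, 677 lost the call, 12 reached it and 33 reversed. The cause was not tested unless stated. With an estimated correlation the X-linked medians of 0.027, 0.28 and 0.299 (P14, P18 testis, spermatocytes) and the age-set medians of −0.646 and 0.251 lost their call. The correlations estimated from the residuals were 0.0465, 0.202 and 0.456 for the X-linked sets. They were 0.342 and 0.159 for the age sets, against the preset 0.01.

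Without a filter, where more genes are tested, P14 had 6 lower, P18 testis 376 higher, spermatocytes 758 higher, the age interaction 37 higher and the fraction interaction 81 lower. With the stricter filter P14 had 4 higher and 226 lower, and with 1 fit over all libraries P14 had 1 and spermatocytes 3808 higher. With the replicate block P14 had 0 and 3, P18 testis 481 higher and the fraction interaction 5 and 82. Same-numbered Het and KO libraries shared only a number, with correlations of their deviations of 0.0837 to 0.104 at P14, −0.027 to 0.0257 in P18 testis and 0.0544 to 0.242 in spermatocytes. Of 3 Het libraries 3, 1 and 3 correlated best with the KO library of their number, a hint from the data and not the design. With the block, among others, the calls of the 9 named genes at P14 and of Hdac1 and Trerf1 in P18 testis ended. With a pseudocount of 0.1 P14 had 1 and 16 and the fraction interaction 375 lower, and with 1 these were 4 higher and 161 lower. With voom P14 had 179 lower, P18 testis 1954 and spermatocytes 2784 higher, the age interaction 4 and 126, and the fraction interaction 8 higher. With median-of-ratios scaling spermatocytes had 2357 higher and the fraction interaction 100 lower. As deposited P18 testis had 2473, spermatocytes 3986, the age interaction 203 and the fraction interaction 58 higher, age in Het 3486 lower and age in KO 7743 higher and 2318 lower. A log2 change of at least 1 left 33 and 1456 in P18 testis, 64 and 2278 in spermatocytes, 8 higher in the age interaction, 1867 and 2003 for age in Het, 753 and 1994 in KO, 721 and 3922 for fraction, and overlaps of 1 and 1309.

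Values that reversed under other settings were, for Hdac1, 0.008 at P14 in 1 fit over all libraries and, in spermatocytes, 0.039 (median-of-ratios), 0.091 (1 fit), 0.2 (as deposited) and 0.046 (voom); for Dnttip1 in spermatocytes 0.032 (1 fit) and 0.141 (as deposited) and in the fraction interaction 0.108 (median-of-ratios), 0.175 (as deposited) and 0.041 (voom). As deposited, age in KO gave 0.066 for Elmsan1, 0.175 for Hdac2, 0.225 for Trerf1, 0.005 for Tex15, 0.045 for Aen and 0.055 for Trim25, and fraction gave −0.054 for Hdac2 and −0.003 for Elmsan1.

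Without single libraries the counts ranged from 0 to 4 higher and 0 to 124 lower at P14, 78 to 1036 and 1414 to 3230 in P18 testis, 473 to 2023 and 2358 to 3365 in spermatocytes, 5 to 230 and 30 to 1535 in the age interaction, 0 to 22 and 20 to 336 in the fraction interaction, 3952 to 4971 and 4597 to 5225 for age in Het, 2335 to 3235 and 3442 to 4386 for age in KO, and 4692 to 5566 and 5593 to 6343 for fraction. The X-linked medians were 0.013 to 0.045, 0.225 to 0.305 and 0.187 to 0.408, and the age sets −0.642 to −0.422 and 0.22 to 0.342. Values that reversed were those of Elmsan1 at P14 (−0.044 to 0.082), Hdac1 at P14 (−0.053 to 0.027) and in spermatocytes (−0.07 to 0.103), Dnttip1 in the fraction interaction (−0.076 to 0.154) and Elmsan1 for fraction (−0.003 to 0.211). The planned count model and its size-factor alternative in DESeq2 were not run, since the values are not counts, and depth limits genes near the value of 1 read.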

Other observations

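No test of this part was planned; the gene classes were looked at only after the result was seen, and their values are given without an explanation. Of 533 long intergenic noncoding RNAs tested in P18 testis 189 fell and 8 rose (median −0.23), against 3232 and 1106 of 18786 over all genes. In spermatocytes 216 of 405 fell and 10 rose (median −0.80), against 4036 and 1492 of 15960 over all genes. No set test was run on these classes. In Het testes 186 of 365 rose and 42 fell between P14 and P18 (median 0.51), against 98 and 42 in KO (median 0.29). Genes annotated as antisense had 215 lower and 38 higher of 1210 in P18 testis and 264 lower and 41 higher of 962 in spermatocytes, and whether their reads came from the antisense strand is unknown, because no strand setting is given in the sources used here.

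Highly abundant short transcripts differed between the sets of libraries. The ribosomal RNA repeat transcript Gm23935 had deposited values of 169152 to 202460 in P18 testis, 34662 to 44067 at P14 and 21487 to 61289 in spermatocytes. AY036118 stood at 30325 to 41821 at P14 and was listed at 0 at P18. Of 1656 processed pseudogenes 1292 fell between P14 and P18 in Het testis and 1291 in KO testis (medians −3.17 and −3.21). Among mitochondrially encoded genes, mt-Cytb (−0.20) and mt-Nd1 (−0.25) moved little with age in Het, and mt-Nd4 moved by −1.42 with 63.53% of its 50-mers shared.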
